A study of Homo sapiens with 6 samples.

How the data were processed

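Gene expression was measured in SH-SY5Y cells, an established human neuroblastoma line of sympathoadrenal type, on 6 Illumina bead arrays, 3 from cells given the vehicle dimethyl sulfoxide (DMSO) and 3 from cells given atrazine, a triazine herbicide. Per the labels, total RNA was isolated with TRIzol and turned into biotinylated cRNA before hybridisation. The dose and the length of the exposure were not given in the sources used here. The labels number the replicates of each group but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

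The authors deposited a table of signal intensity for 22184 probes on each array, with no normalization between arrays that the values show, and beside each intensity a detection p-value, as named per the file headers. They also deposited a table of processed intensity values. These had the same rank order as the raw intensities on every array (Spearman rho of 1), and their sorted values lay within 1% of the mean of the sorted raw intensities for 100% of the probes, which is quantile normalization on the linear scale without background subtraction. The median was 111.5 on every array. The table was therefore used only as an alternative. Nothing in the sources used here gives the scanner software, its version or the chip that held each array.

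The raw intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected with the normexp model, its background inferred from the detection p-values, with an offset of 16. The arrays were then quantile normalized on the log2 scale (the neqc procedure). Of the 22184 probes, 19715 carried 1 gene symbol in the platform annotation, 0 carried several and 2469 had no symbol here. Of the named probes, 19695 were matched to a current gene by gene ID. Each gene was read from 1 probe, the one with the highest mean over all 6 arrays, chosen without regard to group, and unnamed probes stayed as their own features. A feature was kept where its detection p-value was under 0.05 on all 3 arrays of at least 1 group. This left 11838 features, of which 10649 were named genes, and they are called genes below.

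Groups were compared with limma's lmFit and eBayes, two-sided, as atrazine minus DMSO, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. No exact test on single genes with 3 arrays against 3 can reach that threshold, and their smallest two-sided p would be 0.1. A gene with no probe above background (detection p of 0.05 or more) on any array of a group has only a bound there. Its change is given as at least N-fold, from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest normalized value among detected probes and the probe's own value. No fold is given where that ratio was under 1. For arrays, the number of arrays limits the precision.

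Before the data were examined, 29 gene lists were fixed, covering stress responses, insulin signalling, mitochondria, metabolism, the sympathoadrenal lineage and markers of other cell types. A list with at least 5 tested members was compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 26 lists that qualified. The camera result with an estimated correlation and the rotation test fry were run beside it. The genes named in the text were chosen by a rule fixed at the same time. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, without uncharacterised symbols. It also takes up to 3 members of smallest p in each list. Added to these, whatever their values, are 12 genes fixed in advance. They are genes of the themes in the study's title, with CYP1A1 and TH beside them.

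The procedure was tested on simulated data drawn for this comparison with the arrays' own brightness. Among 11211 simulated features, 4-fold changes were called in the right direction in 67.2% of 67 genes, 2-fold changes in 32.8% of 61 and 1.41-fold changes in 0% of 57. Of the 11026 unchanged features, 17 were called (0.154%). With no gene changed, 0 of 11063 were called. These rates hold for few changed genes and need not carry over to data in which most genes differ. Among 26 simulated lists, 1 list shifted by 1.41-fold was called with the preset correlation and 0 with an estimated one. Not passing with an estimated correlation therefore says little about whether a list shifted.

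The alternatives were no background correction, an offset of 50, median scaling, the authors' processed intensities, no detection filter, detection p under 0.01 on all 6 arrays, every probe as its own feature, the mean of a gene's detected probes, an intensity trend with robust estimation, array weights, the replicate number as a block, leaving out each array in turn, other list tests and other thresholds. No scaling between arrays, scaling to the mean of the housekeeping genes, and the comparison of several probes of one gene were added after seeing the data. A block for the chip was not run, because the sources used here do not say which arrays shared a chip. No genome was used, so no positions are given.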

Results

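The data were 6 arrays of RNA from SH-SY5Y neuroblastoma cells, 3 after the vehicle DMSO and 3 after atrazine. The study's title places the comparison in the setting of stress of the endoplasmic reticulum (ER), insulin signalling and damage to mitochondria. The mean signal per array was 586.6, 939.1 and 532.2 intensity units in DMSO, and 235.1, 254.0 and 311.3 in atrazine. Of the 22184 probes, 58.9% to 59.8% were above background on the DMSO arrays, against 50.6%, 43.6% and 52.0% on atrazine arrays 1, 2 and 3. The 100 brightest probes held 11.9% to 16.8% of the signal above background in DMSO and 24.1% to 27.3% in atrazine. Across genes, which are not independent replicates, normalized values correlated at r = 0.992 to 0.995 between DMSO arrays and at 0.994 between atrazine replicates 1 and 3. Atrazine replicate 2 correlated with these at 0.968 and 0.963, and the between-group values ran from 0.805 to 0.888.

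**Figure D1:**
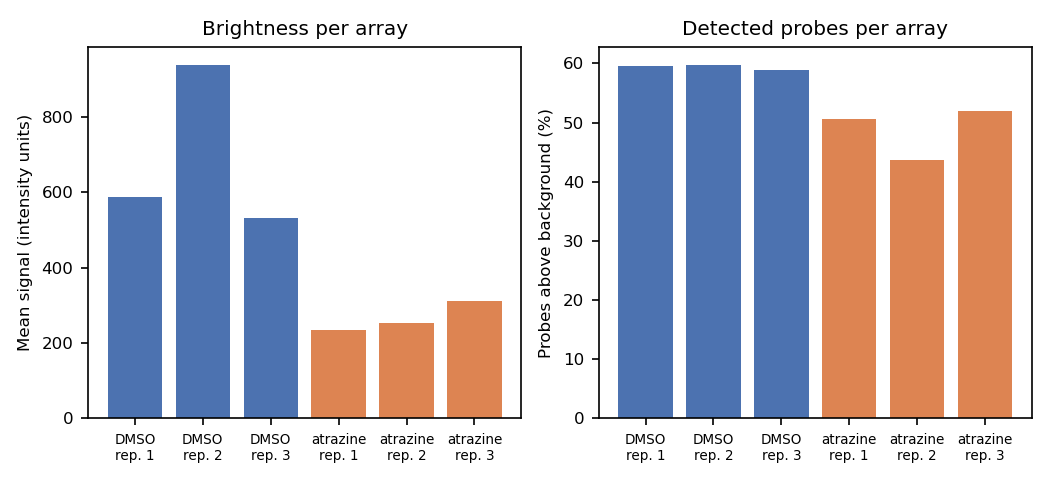
Mean raw signal in intensity units (left) and percent of probes above background (right), 1 bar per array, blue for DMSO and orange for atrazine. The 3 atrazine arrays, at 235.1 to 311.3 units, were dimmer than the 3 DMSO arrays, at 532.2 to 939.1, and had fewer detected probes.

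Arrays of atrazine-treated cells differed from arrays of vehicle-treated cells in most of the genes measured, each read from 1 probe. A technical difference between the groups of arrays stays open beside the treatment, as described below. The largest rise among named genes was that of RENBP, an enzyme of amino sugar metabolism (probe ILMN_1780057), from 5.82 ± 0.69 in DMSO to 12.32 ± 0.18 in atrazine (log2 intensity, mean ± SD, n = 3). NRROS rose by 6.47 on the log2 scale, the synaptic vesicle protein gene SYNGR1 by 6.16, the histone variant gene H2AJ by 5.45 and the lectin gene SIGLEC12 by 5.44. CEBPB, a stress- and cytokine-responsive transcription factor (probe ILMN_1693014), rose from 8.52 ± 0.49 to 13.84 ± 0.09 (limma adjusted p = 4.56e-06), and SOD2, the superoxide dismutase of mitochondria, from 7.89 ± 0.33 to 13.10 ± 0.12. MGST2, a microsomal glutathione transferase, was not above background in DMSO and was at least 34.3-fold higher in atrazine. The splicing regulator MBNL2 (5.22) and the methyltransferase gene CARNMT1 (4.97) completed the 10 largest rises. RENBP, NRROS, SYNGR1, SIGLEC12 and CARNMT1 were above background on only 2 of 3 DMSO arrays, so the sizes of their rises are less certain.

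The largest falls were smaller than the largest rises. CYREN, a regulator of DNA end joining, went from 8.94 to 5.64, a log2 change of -3.30 (SE 0.19), and the splicing factor SFPQ changed by -3.06. The protease PAPPA (-2.92), the spindle protein DLGAP5 (-2.84), the focal adhesion protein TNS3 (-2.72) and the adhesion receptor ADGRB3 (-2.58) also fell. TM4SF4, MAP3K13, LANCL2 and MPHOSPH8 were not above background on any atrazine array and were at least 4.37-, 5.13-, 4.52- and 4.47-fold lower. CYREN, SFPQ, DLGAP5 and TNS3 were above background on only 2 of 3 atrazine arrays and PAPPA on 1, so the sizes of their falls are less certain.

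In all, 7951 of 11838 genes passed the threshold (67.2%), 3264 higher and 4687 lower in atrazine, and 5647 of these changed by 1.5-fold or more. Changes of 8-fold or more were 82 rises and 2 falls. The groups did not overlap in 8880 genes (75.0%, where chance gives 10%). Without atrazine replicate 2, which stood apart, 8624 genes passed, 3562 higher and 5062 lower. The balance of directions moved with the scaling, since the median log2 change of all genes was -0.18 after quantile and -0.94 after median scaling. Of the calls, 41.1% were rises in the first case and 17.4% (1748 higher, 8278 lower) in the second. Housekeeping scaling stayed close to the first, with a median of -0.18 and 42.6% rises (3646 higher, 4913 lower). Of the 7951 calls, median scaling kept 75.3% and called 811 in the other direction. Housekeeping scaling kept 75.6% and reversed 368, and no scaling kept 61.3% and reversed 1222. Between these 3 scalings all log2 changes shift by one constant (each correlated at 0.878 with the main values), so their reversals are not separate evidence. The balance also moved with the detection filter. Of the 8509 genes above background on all 6 arrays, 2797 were higher and 2653 lower, and the median of all genes was -0.011 with a stricter detection on all arrays and -0.0083 without a filter. Counts for gene groups are therefore followed by those under median scaling, and medians called relative are differences from the median of all genes in that setting.

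A further measured limit applies to every gene named here. In 476 genes with at least 2 probes above background on all 6 arrays, the log2 changes of the 2 brightest probes correlated across genes at only r = 0.14 (Spearman rho 0.18), and 62.0% of the 208 pairs in which both passed had one direction. Where both also changed by 2-fold or more, 25 of 31 pairs (80.6%) did. MBNL2, which is outside these pairs because its second probe was above background on only 2 atrazine arrays, rose by 5.22 on its brightest probe and changed by -1.33 on the other. The brightest probe of SYNGR1 was likewise left out (above background on 2 DMSO arrays), and 2 of its 3 further probes gave -0.03 (not past the threshold) and 0.95, while the remaining one did not pass the detection filter. Both probes of HSPA8 fell (-1.03 and -1.27), as did both of TIMM23 (-0.82 and -0.75). For SOD2, SIGLEC12, AIF1, PTPRC, KEAP1, CDKN1A, SREBF1, OASL and AKT1, no further probe passed the detection filter. These further probes are on the array but were not above background on all 3 arrays of either group. The changes of these genes were thus seen on 1 probe only. This holds also where that probe was bright in atrazine, as for SOD2 (13.10) and SIGLEC12 (10.87).

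**Figure D2:**
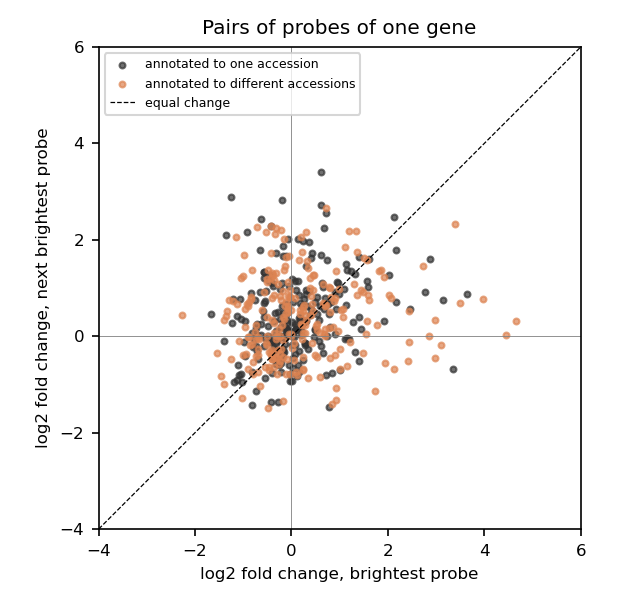
Log2 fold change (atrazine minus DMSO) of the brightest (horizontal) and next brightest (vertical) probe of a gene among its probes above background on all 6 arrays, 1 point per gene for 476 genes, dark for pairs annotated to one accession and orange for different accessions, with the dashed line marking equal change. The points scatter around no diagonal, with r = 0.14 over all pairs.

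Genes of ER protein folding went both ways, with more falls than rises. HSPA5, which encodes the ER chaperone BiP (probe ILMN_1773865), fell from 8.62 ± 0.05 to 6.58 ± 0.04, a log2 change of -2.05 (SE 0.09, adjusted p = 5.32e-06). Every atrazine array lay below every DMSO array for HSPA5, and 75.0% of all genes had groups that did not overlap. The disulfide isomerase PDIA6 rose by 2.51 and the oxidase ERO1B by 1.26. Of 33 tested genes of ER chaperones, folding enzymes and ERAD (the disposal of misfolded ER proteins), 7 rose, 15 fell and 11 did not pass (3 rises and 28 falls under median scaling). Adjusted over the list alone, 7 rose and 17 fell. The list's median was -0.28 (-0.25 with genes near background set at their bound). Relative to all genes it was -0.10 (-0.46 under median scaling), and camera's adjusted p was 0.47. XBP1, a transcription factor of the unfolded protein response, changed by 0.43 (SE 0.14, adjusted p = 0.029). That call was lost without DMSO replicate 1 (0.076), DMSO replicate 3 (0.057) or atrazine replicate 3 (0.087). Under median scaling XBP1 turned to -0.75 and passed (adjusted p = 0.0071).

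Among the targets of ATF4 and CHOP, transcription factors of the integrated stress response, CEBPB led, followed by DDIT4, an inhibitor of mTOR signalling (1.85), and the secreted stress factor GDF15 (2.05). Of 29 tested members 10 rose, 8 fell and 11 did not pass (6 rises and 21 falls under median scaling). The list's median was -0.02 while its mean was 0.32 and camera's direction up (adjusted p = 0.44). Relative to all genes the median was 0.16, -0.17 under median scaling, -0.0076 with detection on all arrays and -0.010 without the filter. DDIT3, which encodes CHOP, changed by 0.35 (SE 0.12, adjusted p = 0.033), and by -0.54 under median scaling, which also passed (adjusted p = 0.0031). The call of its rise was lost without DMSO replicate 2 (adjusted p = 0.11), DMSO replicate 3 (0.077) or atrazine replicate 3 (0.079). ATF4 itself gave -1.21 (SE 0.42, adjusted p = 0.036) on its brighter probe and 0.78 on the other. The former was -0.66 without atrazine replicate 2, and was no longer past the threshold without DMSO replicate 1 (0.12), 2 (0.079) or 3 (0.056).

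Cytosolic heat shock genes mostly fell. HSPH1 changed by -1.65, HSPA8, the constitutive HSP70, by -1.03 and HSPA1B, an inducible one, by -0.91. Of 15 tested members 3 rose, 9 fell and 3 did not pass (1 and 11 under median scaling), and camera's adjusted p was 0.40 at a relative median of -0.46 (-0.71 under median scaling).

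Genes of insulin signalling changed in both directions in similar numbers. The receptor gene INSR rose by 0.93 (SE 0.09, adjusted p = 1.34e-04) from a low level of 5.57 in DMSO. AKT1, the kinase downstream of it, rose by 0.91 (SE 0.11), but gave -0.21 under median scaling, which did not pass. The transcription factor gene FOXO4 rose by 3.32 and the exchange factor gene SOS1 by 1.91, while SLC2A1, the glucose transporter GLUT1, was not above background in atrazine and was at least 2.52-fold lower. The adaptor gene IRS2 fell by 0.43 on the log2 scale (SE 0.11, adjusted p = 0.0081). IRS1 was above background on 3 of 3 DMSO arrays and on 0 atrazine arrays, too close to background for a fold, and its call was lost without DMSO replicate 2 (adjusted p = 0.063) or 3 (0.057). Under housekeeping scaling it turned to 0.43 and passed (adjusted p = 0.022). Over the list, 13 of 39 tested members rose, 15 fell and 11 did not pass (8 and 25 under median scaling). The median was -0.16 (-0.09 with genes near background set at their bound) and the mean 0.11, and camera, whose direction was up, gave an adjusted p of 0.74.

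**Figure D3:**
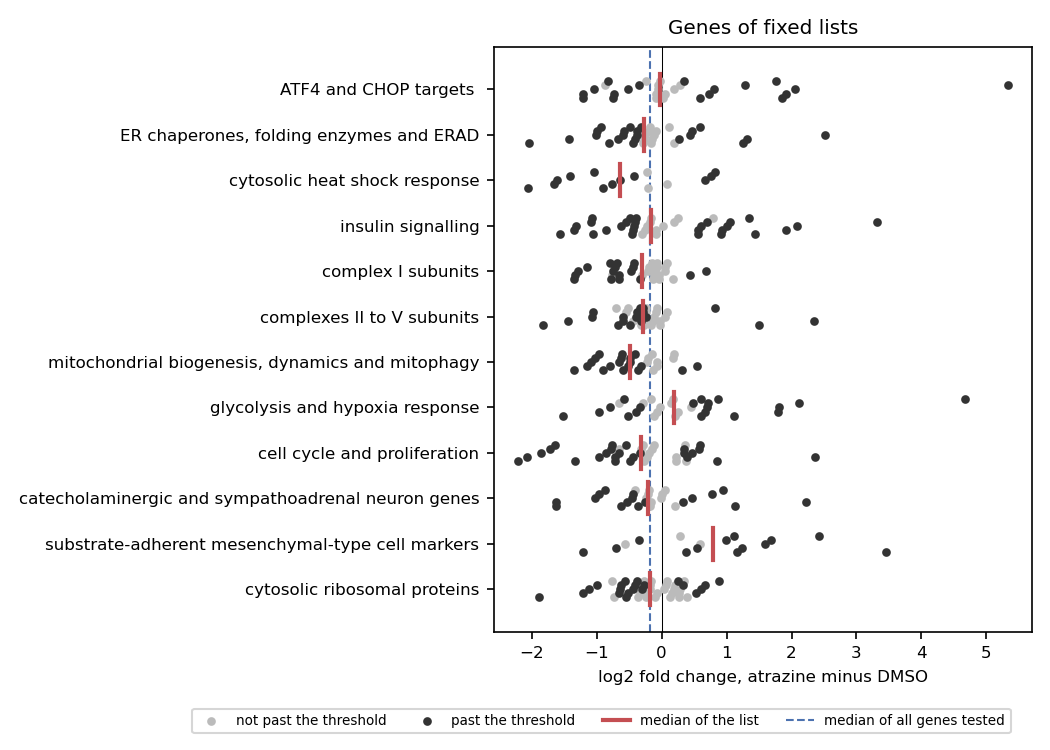
Log2 fold change (atrazine minus DMSO, horizontal) of each tested gene in 12 fixed lists (rows), dark where past the threshold and grey where not, with the list's median as a red bar and the median of all genes tested (-0.18) as a dashed line. Most lists hold rises and falls, and the mesenchymal-type markers lie furthest to the right.

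Nuclear genes of the respiratory chain fell more often than they rose, as did all genes tested (4687 falls and 3264 rises among 11838). In complex I, which oxidises NADH, 2 of 33 tested subunit genes rose and 15 fell (0 and 31 under median scaling; 1 and 14 adjusted over the list alone), and 16 did not pass. NDUFV3 and NDUFS1 were not above background in atrazine and were at least 1.36- and 1.51-fold lower, and NDUFB2 changed by -0.78. The list's median was -0.12 relative to all genes and -0.32 under median scaling. Camera's adjusted p was 0.18, and 0.018 under median scaling (adjusted p = 0.997 with an estimated correlation). In complexes II to V, 3 of 37 rose, 16 fell and 18 did not pass (2 and 35 under median scaling; 3 and 12 adjusted over the list alone), with camera's adjusted p at 0.36. Without the detection filter both lists passed (0.021 and 0.038), but not with an estimated correlation (0.35 for both). The ATP synthase genes ATP5MG (5.07-fold) and ATP5F1C (2.82-fold) rose, whereas ATP5MC3 was not above background in atrazine and was at least 1.60-fold lower. No gene of the mitochondrial genome was analysed here.

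Genes of mitochondrial biogenesis, dynamics and mitophagy fell in 17 of 27 cases and rose in 2, and 8 did not pass (26 falls and 0 rises under median scaling). Prohibitin PHB1 changed by -1.08, the coactivator PPRC1 by -0.65, and TFB2M, a factor of mitochondrial transcription, by -0.60. TFAM, which packages mitochondrial DNA, changed by -0.51 (SE 0.12, adjusted p = 0.0061). The median was -0.31 relative to all genes and -0.64 under median scaling. Camera's adjusted p was 0.18 and, under median scaling, 0.024 (adjusted p = 0.997 with an estimated correlation). PPARGC1A, the biogenesis coactivator PGC-1alpha, was above background on 0 of 6 arrays. Of 20 genes of mitochondrial protein folding and import, 3 rose, 10 fell and 7 did not pass (1 and 18 under median scaling; camera's adjusted p = 0.44). The protease HTRA2 rose by 2.42 on its brighter probe and gave -0.52 on the other, TIMM23 changed by -0.82, and TIMM17A was at least 1.07-fold lower, a direction that turned under housekeeping scaling (0.060, not past).

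Glycolysis and hypoxia genes rose in 12 of 30 cases and fell in 7, and 11 did not pass, but 4 rose and 18 fell under median scaling (camera's adjusted p = 0.18). The relative median was 0.37, and 0.35 under median scaling. PKM, pyruvate kinase, rose by 4.67 on its brighter probe and gave 0.31 on the other, which did not pass. ALDOC rose by 1.81 and EGLN1, an oxygen-sensing hydroxylase, by 1.79. In the NRF2 antioxidant response, 2 of 17 rose and 6 fell, and 9 did not pass (1 and 15 under median scaling; camera's adjusted p = 0.74). NQO1, a quinone reductase, was at least 1.38-fold lower, PRDX1 changed by -0.73 and KEAP1 by -0.68. CYP1A1, the classic target of the aryl hydrocarbon receptor, was above background on 0 of 6 arrays. Of 7 tested genes of that receptor and of xenobiotic receptors, 2 rose, among them ARNT (1.57), and 4 fell (1 and 5 under median scaling; camera's adjusted p = 0.74). CYP1B1 was above background in DMSO only, too close to it for a fold, and turned to 0.32 (not past) under housekeeping scaling.

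In the sympathoadrenal lineage, TH and DBH, enzymes on the path to dopamine and noradrenaline, moved in opposite directions. TH rose by 0.95 (SE 0.09, adjusted p = 1.28e-04) from a low 5.58, and DBH fell from 12.77 to 11.14, a log2 change of -1.63. INSM1 rose by 2.22, and GAP43, a growth cone protein, by 1.13 (-0.079, not past, under median scaling). Of 27 catecholaminergic and sympathoadrenal genes 6 rose, 11 fell and 10 did not pass (3 and 18 under median scaling; camera's adjusted p = 0.74). Genes of the neuronal cytoskeleton and synapse split evenly, with 8 rises and 8 falls among 25 (1 and 17 under median scaling; camera's adjusted p = 0.74). Their median was -0.19 while camera's direction was up. DLG4 rose by 1.56, NEFH changed by -1.01 and HOMER1 was at least 1.01-fold lower, a direction that turned under housekeeping scaling (0.069, not past).

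Cell cycle genes fell in 17 of 37 cases and rose in 8, and 12 did not pass (35 falls and 1 rise under median scaling; 18 and 9 adjusted over the list alone). The list's median was -0.32, against -0.18 over all genes tested, which also fell more often than they rose. MCM6, a subunit of the replicative helicase, was at least 2.27-fold lower and cyclin D1, CCND1, changed by -1.64, while the mitotic kinase PLK1 rose by 2.36. Camera's adjusted p was 0.44 and, under median scaling, 0.032 (adjusted p = 0.997 with an estimated correlation). Among p53 targets, BBC3 (2.28) and CDKN1A (2.08), which encode the pro-apoptotic PUMA and the cell cycle inhibitor p21, rose. TP53I3 was not above background in atrazine on its brighter probe and gave 0.31, not past, on the other. Of 19 tested, 8 rose, 5 fell and 6 did not pass (2 and 14 under median scaling; camera's adjusted p = 0.40). Of 20 immediate early and cAMP-responsive genes, 9 rose, 7 fell and 4 did not pass (4 and 9 under median scaling; camera's adjusted p = 0.56). EGR1 was at least 2.91-fold lower, DUSP6 changed by -1.66 and FOSL2 rose by 1.52. The median of that list was 0.35 while its mean was -0.03 and camera's direction up.

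No tested list of markers of other cell types passed camera in the main setting, and those under 5 tested members were not tested as lists. Of 16 tested markers of the substrate-adherent mesenchymal-type cells that neuroblastoma lines can hold, 10 rose, 3 fell and 3 did not pass (5 and 4 under median scaling; 11 and 3 adjusted over the list alone). S100A6 rose by 3.46, COL1A1 by 2.43 and COL5A1 by 1.68. Camera's adjusted p was 0.051 (adjusted p = 0.58 with an estimated correlation), and it was 0.047 without DMSO replicate 2, 0.0498 without DMSO replicate 3 and 0.039 without atrazine replicate 2 (0.74, 0.63 and 0.58 with an estimated correlation). Over 19 alternatives it ran from 0.0043 to 0.064 and passed in 13, and with an estimated correlation it passed in 0 (0.33 to 0.996). All 4 tested Schwann and glial markers rose, among them SOX9 (1.36), FABP7 (0.64) and GAP43, counted above among neuronal genes and the only one that did not rise under median scaling. Without atrazine replicate 2 this list had 5 tested members and passed (adjusted p = 0.034), as it did with 12 members without the detection filter (0.029), but not with an estimated correlation (0.58 and 0.35). Of 13 blood and immune markers on the array, AIF1 and PTPRC alone were tested, having been detected in atrazine. Neither was above background in DMSO, and they were at least 6.99- and 1.58-fold higher. Of 8 epithelial markers 2 rose, 2 fell and 4 did not pass (2 and 1 under median scaling; camera's adjusted p = 0.75, direction up, at a median of -0.03), with CLDN7 at least 2.01-fold higher. KRT18 rose by 1.13 on its brightest probe. Its next probe gave -0.72, past the threshold, and was not above background in atrazine, while a further one did not pass the detection filter. KRT8 was above background in DMSO only, too close to it for a fold. It did not pass under median scaling (adjusted p = 0.11) and turned to 0.36 (not past) under housekeeping scaling.

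Cytosolic ribosomal protein genes rose in 6 of 45 cases and fell in 15, and 24 did not pass (7 and 20 under median scaling; 4 and 12 adjusted over the list alone). RPS9 rose by 0.88, RPL29 changed by -1.11 and RPL28 by -0.62. Relative to all genes the median was 0.01 after quantile and 0.66 after median scaling, and camera's adjusted p was 0.76. Of 14 housekeeping genes, 2 rose, 3 fell and 9 did not pass (1 and 9 under median scaling; 2 and 2 adjusted over the list alone). Their median was 0.06 and their mean -0.05, with camera's adjusted p at 0.74 and its direction up. The transferrin receptor TFRC changed by -1.87, HPRT1 by -0.71, and SDHA by 0.81 (-0.39, past the threshold, under median scaling).

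Of the 26 lists tested, camera with a preset correlation called 0, with 5 at an unadjusted p under 0.05, and with an estimated correlation it also called 0. Fry called 19, 9 upward and 10 downward, which says that genes of a list moved on balance one way and not that the list differed from other genes. Under median scaling camera called 6 lists, with complex I, mitochondrial biogenesis and cell cycle genes lower than other genes, and mesenchymal-type (adjusted p = 0.010), epithelial (0.027) and interferon-stimulated genes (0.011) higher. With an estimated correlation none of these passed, and over all lists and alternatives no adjusted p was then below 0.33. That setting also missed the shifted list in the simulation, so no conclusion is drawn from its calling none. Except where given, counts adjusted over the list alone were those over all genes.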

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

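Leaving the arrays unscaled and scaling them to the housekeeping genes were chosen after seeing the data. The count of genes past the threshold stayed within 1.5 times of 7951 under all alternatives except detection on all 6 arrays, which tested 5911 genes and gave 3795, with 1967 higher, 1828 lower and 2242 changed by 1.5-fold. Median scaling gave 1748 higher, 8278 lower and 8868 changed by 1.5-fold, and no scaling gave 290, 9251 and 9541. Housekeeping scaling gave 3646, 4913 and 6788. Without each array in turn the ranges were 6813 to 8624 genes, 2844 to 3562 higher, 3945 to 5062 lower and 5061 to 6032 by 1.5-fold. The replicate number as a block gave 6870 genes, 2863 higher, 4007 lower and 5561 by 1.5-fold, with 0 lists. Of the named genes it ended the call of DDIT3 only (0.35, adjusted p = 0.096). Deviations of same-numbered arrays from their group means correlated at -0.18, -0.45 and -0.29. Those of differently numbered arrays correlated at -0.21 to 0.44. Same-numbered arrays thus did not deviate together. Deviations within a group depend on one another, so they cannot show whether same-numbered samples shared a day or culture.

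Against 0 lists, 1 list, that of mesenchymal-type markers, passed with no background correction, an offset of 50, the authors' values, detection on all arrays, every probe, the mean of probes, array weights or lists of 10 or more members. Without a detection filter 3 passed, with median, housekeeping or no scaling 6, and with fry 19. Without each array in turn 0 to 3 passed. The cause was not tested.

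Over all alternatives, 1929 values of the 108 named genes kept their direction and their side of the threshold, 44 kept the direction only and 28 reversed. Of these genes, 104 passed without each array in turn, and 96 kept their direction under quantile, median and housekeeping scaling. Under median scaling these reversed: HSD17B4 (-0.18), INSIG1 (-0.47), GAP43 (-0.079), SDHA (-0.39), DDIT3 (-0.54), XBP1 (-0.75) and AKT1 (-0.21), and SREBF1, SREBF2 and KRT8 no longer passed. Of the reversed values there, those of INSIG1, SDHA, DDIT3 and XBP1 passed the threshold. With no scaling, which differs from median scaling by one constant for all genes, reversed values were EGLN1 -0.028, ARNT -0.10, HSD17B4 -0.89, SREBF1 -0.53, SREBF2 -0.62, INSIG1 -1.19, FOSL2 -0.079, GAP43 -0.79, DLG4 -0.30, FABP7 -0.10, KRT18 -0.060, SDHA -1.10, DDIT3 -1.25, XBP1 -1.46 and AKT1 -0.92. Under housekeeping scaling, a further such constant, they were TIMM17A 0.060, CYP1B1 0.32, HOMER1 0.069, KRT8 0.36 and IRS1 0.43, the last past the threshold, and with the mean of probes INSIG1 -0.23. The cause was not tested. A block for the chip was not run. Of the lower genes, 1119 were not above background on any atrazine array and have a bound only.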

Other observations

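The tests of rows out of place and of a larger response in atrazine replicate 2 were chosen after the results they bear on had been seen, as was the comparison of several probes of one gene. In the lists not described above, interferon-stimulated genes rose in 6 of 9 tested cases and fell in 1 (5 and 3 under median scaling; 7 and 1 adjusted over the list alone), led by IFITM1 (3.39) and OASL (1.65), while IRF1 was at least 1.38-fold lower. Camera's adjusted p was 0.094 (adjusted p = 0.58 with an estimated correlation), and 0.04998 without atrazine replicate 2 (adjusted p = 0.66 with an estimated correlation). Autophagy and lysosome genes fell in 15 of 29 cases and rose in 8 (22 and 4 under median scaling; 15 and 9 adjusted over the list alone; adjusted p = 0.98), with a median of -0.37 and a mean of 0.04. The lysosomal membrane gene LAMP2 rose by 4.44 on its brightest probe, gave 0.03 on the next, which did not pass, and rose by 2.24 on a further probe. WIPI1 rose by 1.79 and NBR1 by 1.78. A second NBR1 probe gave -0.67, past the threshold, and was not above background in atrazine.

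In the BCL2 family, 5 of 19 tested genes rose and 8 fell (3 and 12 under median scaling; adjusted p = 0.74), with a median of -0.03 (0 with genes near background set at their bound) and a mean of 0.06. BCL2L1, which encodes the survival protein BCL-XL, rose by 2.44 on one probe and gave 0.52 on the other, which did not pass. The pro-apoptotic gene BID changed by -2.48 on its brighter probe. Its other probe gave -0.31, which did not pass, and was not above background in atrazine. Of 10 steroidogenesis genes, 5 rose and 2 fell (3 and 6 under median scaling; adjusted p = 0.40). POR rose by 2.09, NR5A1, the steroidogenic regulator SF1, by 1.41, and HSD17B4 by 0.97 (-0.18 under median scaling, not past). Cholesterol synthesis genes gave 7 rises and 5 falls among 21 (0 and 18 under median scaling; adjusted p = 0.44), with SREBF2 at 1.28 and SREBF1 at 1.18 (0.095 and 0.18 under median scaling, neither past), and INSIG1 at 0.70, which was -1.16 on its second probe and -0.47 under median scaling (adjusted p = 0.034). Of 13 histone genes 5 rose and 6 fell (3 and 6 under median scaling; adjusted p = 0.79), with a median of -0.20 (0 at their bound) and a mean of 0.17. H2BC4 was not above background in DMSO and was at least 14.5-fold higher, H2AZ1 rose by 0.95 and H4C14 changed by -1.64.

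The breadth of the difference, 7951 genes, may have a technical part, since the atrazine arrays were dimmer. If brightness were the cause, the brightest DMSO array minus the dimmest should have followed, gene by gene, the difference between the third DMSO array and atrazine with a slope of 0.3 or more. The slope was 0.059 (95% bootstrap interval 0.055 to 0.063 over 11838 genes). Over the range that the DMSO arrays span (mean signal 532.2 to 939.1), this argues against brightness as the main cause. All atrazine arrays were dimmer than that range (235.1 to 311.3), so the test cannot decide what their lower brightness did. The 6 arrays can be split in only 10 ways, too few for a share under 0.05, and only the real split gave as many genes. The highest count of the other splits was 0 genes past the limma threshold (100 at an unadjusted p under 0.05, against 8339). Every other split mixes DMSO and atrazine arrays on each side, so the group difference adds to the spread within its sides. Low counts there cannot show how many genes chance would give, and no conclusion is drawn from them. A difference of chip, hybridisation day or RNA quality was not tested, since no label gives one, and each stays open beside the treatment itself, as fewer probes were detected in atrazine (43.6% to 52.0%) and the 100 brightest held more of the signal.

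The low agreement between probes of one gene (r = 0.14) could come from noise, from transcripts that differ between probes or from rows out of place in one group. Noise is argued against, since fold changes of the same 952 probes from separate arrays correlated at 0.954. Pairs annotated to one accession should have correlated at 0.7 or more if only the choice of transcript mattered, but gave 0.21 (95% interval 0.08 to 0.33, 234 genes). Exchanged rows should give as many 8-fold falls as rises, whereas the ratio over all probes was 0.035 (3 falls, 85 rises). The counts for genes (82 rises, 2 falls) were known when this test was chosen. It bears only on rows exchanged with each other, and other ways for rows to be out of place were not tested. Probe sequences and positions were not used here, so other probe-specific signal, such as changes in RNA ends or binding of other transcripts, stays open as untested, and a gene read from 1 probe is best taken as a hypothesis about that gene.

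Atrazine replicate 2 stood apart from the other atrazine arrays. Noise near background is argued against, because in the 2960 brightest genes the SD of its difference from replicate 3 was 2.98 times that of replicate 1 from replicate 3. A larger response in the same direction is a candidate explanation for part of it. Its difference from replicate 3 followed the change of replicate 1 from DMSO with a slope of 0.16 (95% interval 0.15 to 0.18), which accounts for 8.47% of its variance. What the remainder reflects was not tested.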
